A study of Homo sapiens with 12 samples.

How the data were processed

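RNA from 12 samples of SH-SY5Y neuroblastoma cells with an inducible FOXO3A transgene was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per sample, in 4 groups of 3. The deposited values are probe set signals on a linear intensity scale, made by the authors with MAS5 in GCOS, per the submitters' processing notes, which give no versions in the sources used here. The intensity table that the authors deposited holds 54675 probe sets to 1 decimal. Its mean after trimming 2% at each end was 100 on every array, so all arrays had been scaled to 1 target. No detection call was used here. No pair of arrays shared more than 1.76% identical values, and arrays of 1 group correlated at 0.971 to 0.985, so each was counted as 1 sample.

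Groups and replicate numbers were taken from the sample labels. The 62 control probe sets were left out. Gene names came from the platform's probe table: 41091 probe sets had 1 symbol, 1801 had several and 11721 had none given there, and only probe sets with 1 symbol named a gene. Of these, 41043 matched a symbol in the RefSeq gene table and 0 needed an update. Signals were tested as log2(signal + 2), the offset being the 20th percentile of all signals, with the authors' scaling kept. Probe sets with a mean at or below the 40th percentile (log2 3.27, a signal of 7.62 with the offset removed) were left out, which kept 32768. The probe set with the highest mean stood for each gene, and 6900 genes had several. Where another probe set of a gene described as past the threshold, with or without a replicate block, went the other way, its value is given with the gene at least once. Probe sets that went the same way by less are given for some genes only. This left 13714 genes. Of the genes on the fixed lists, 29 were below the filter, 13 were in probe sets that list several genes only, BBC3 among them, and 35 had no row in the probe table used here, PIK3CA among them. These were not analysed here.

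A linear model with a mean for each group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, and p-values were adjusted with the Benjamini-Hochberg method over genes, with a threshold of 0.05. The comparisons were each treatment without and with the other, their interaction, both together against control, and each averaged over the other. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists fixed beforehand, and again with a correlation estimated per list. Camera compares a list with all other genes. Some lists share members, so their calls are not separate findings. Tested genes shared with the FOXO target list include CDKN1A and SESN1 of the p53 target list. In the autophagy and lysosome list they include GABARAPL1, MAP1LC3B and ATG14, and in the receptors list IRS2, INSR, ERBB3 and RICTOR. In the cell cycle brakes list they include CDKN1A, CDKN1B, RBL2, CCNG2, GADD45A and BTG1. No fixed list was tested without its shared genes. Genes were named by a rule: in each comparison the 8 that rose and the 8 that fell most among those past the threshold whose groups did not overlap (for the interaction 6 on each side, with no rule on overlap), up to 3 members of each list with the smallest adjusted p past the threshold, and 15 genes always. These genes were BCL2L11, BBC3, PMAIP1, CDKN1A, CDKN1B, CCNG2, IRS2, INSR, PIK3CA, RICTOR, SESN3, TXNIP, KLF6, MYCN and CCND1. Values of every FOXO3 probe set were given too, with limma p-values adjusted over all non-control probe sets and no filter. The design, lists, naming rule and alternatives were fixed before the data were examined. Where a comparison had 5 or fewer calls with the replicate block these were named too, as were the interaction genes with the smallest blocked adjusted p, both chosen after their values were seen.

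The replicate numbers pair the arrays. Deviations from the group means correlated at 0.314 to 0.659 in the 18 pairs of arrays with the same number, all above the 0.1 set for pairing, and at -0.459 to 0.195 between numbers. Each of the 12 arrays correlated best with an array of its own number, and the first principal component (35.4% of variance) set replicate number 3 apart. The pairing comes from the replicate numbers in the labels and this check. The fit with the number as a block gives the same fold changes with smaller errors, a median SE of 0.12 against 0.21 for a comparison of 2 groups, and, for each treatment without and with the other and their interaction, its values stand beside the described genes and lists whose call it changes.

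The fits were tested on simulated data, in which 200 of 13714 genes were changed in 5 runs. For PI-103 without doxycycline 46.6% of changes of 1 on the log2 scale were recovered, and 76.4% with the block. For doxycycline without PI-103 these shares were 48.1% and 77.9%, for PI-103 with doxycycline 43.6% and 70.1%, for doxycycline with PI-103 43.3% and 74.3%, and for the interaction 14.0% and 59.1%. False genes made up 0% to 0.634% of the calls without the block and 3.85% to 5.64% with it. The simulated replicate effects and errors came from the blocked fit, so a gain with the block was built in. Correlations of effects that share arrays were set beside 20 simulations of unchanged groups, with the spread left by the fit without and with the block. Alternatives were an offset of 0.5 or 8, quantile normalization, median centring, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, no intensity trend, only the groups compared, the replicate block, each array left out in turn, and a change of at least 2-fold. The runs with 1 array left out had no block, so they also left the replicate numbers unequal between groups. A call that ended there may reflect that imbalance as well as the array itself. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.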

Results

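Gene expression was measured on Affymetrix U133 Plus 2.0 arrays in SH-SY5Y cells, an established human neuroblastoma line, that carried the tetracycline repressor and a tagged FOXO3A transgene. FOXO3A is a forkhead transcription factor that PI3K/AKT signalling phosphorylates and keeps out of the nucleus. Doxycycline (0.1 µg/ml for 24 h) switched the transgene on, and PI-103 (1 µM for 6 h), an inhibitor of PI3K and mTOR, was set against DMSO. The 4 groups were control, PI-103 alone (PI-103), doxycycline alone (dox) and doxycycline with PI-103 (dox+PI-103), each with 3 arrays made over 3 months. The series title places the question in the inactivation of FOXO3A by this pathway in aggressive neuroblastoma. The number of arrays limits the precision, and the labels do not say whether the arrays of a group came from separate cultures, so p-values measure the spread between these arrays. The median signal was 13.9 ± 2.08 in control, 14.6 ± 2.03 in PI-103, 14.0 ± 1.99 in dox and 14.5 ± 2.21 in dox+PI-103 (SD, n = 3 here and for each group mean below). Fold changes are on the log2(signal + 2) scale, which understates the change of dim genes.

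The 7 probe sets for FOXO3, the gene behind the transgene, were read first. Of the 3 that list both FOXO3 and FOXO3B, the dimmest had a signal of 0.967 ± 0.231 in control, 4.33 ± 4.52 in PI-103, 24 ± 6.5 in dox and 37.3 ± 14.9 in dox+PI-103, and all 6 doxycycline arrays lay above all others. Across the 6 same-number pairs with and without doxycycline it was higher with doxycycline in 6 of 6 pairs (two-sided exact sign-flip test, p = 0.0312, adjusted p = 0.0624 over 14 tests). That p is the smallest that 6 pairs allow. The 6 pairs come from 3 replicate numbers and the test takes them as independent, so these exact p-values may be too small. No fold is given, since most arrays without doxycycline lay below the offset of 2. The next had 30.1 ± 21.9 in control, 41.1 ± 34.7 in PI-103, 71.6 ± 41 in dox and 112 ± 67.9 in dox+PI-103, and was 2.66-fold higher with doxycycline. The brightest of the 3, at 71.1 ± 55.8, 98.3 ± 65.6, 76.4 ± 51.9 and 111 ± 68 in the same order, was 1.14-fold higher, and both were higher in 6 of 6 pairs (exact p = 0.0312, adjusted p = 0.0624). The limma p-values here were adjusted over all non-control probe sets with no filter, so over more tests than for genes. In limma the dimmest, though higher on every dox array than on every control array, did not pass with doxycycline in the absence of PI-103 (adjusted p = 1, and 0.18 with the replicate block), and passed in its presence only with the block (0.064, and 0.0057 with the block). So did the middle one with doxycycline in the presence of PI-103 (0.65, and 0.00035 with the block) and with PI-103 in the presence of doxycycline (0.8, and 0.023 with the block). The brightest passed only with the block with PI-103, without doxycycline (0.91, and 0.013) and with it (0.81, and 0.0037). Of the 4 probe sets that list FOXO3 alone, the brightest had 747 ± 385 in control, 1050 ± 411 in PI-103, 817 ± 438 in dox and 1270 ± 378 in dox+PI-103. The next had 230 ± 119, 324 ± 123, 249 ± 122 and 389 ± 118 in that order, and the one after it 156 ± 78.3, 216 ± 90.2, 181 ± 102 and 291 ± 114. With doxycycline these 3 differed by 1.16-fold, 1.15-fold and 1.24-fold, each in 5 of 6 pairs (exact p = 0.0625, adjusted p = 0.0729). With PI-103 each was 1.54-fold higher, in 6 of 6 pairs (exact p = 0.0312, adjusted p = 0.0624). In limma they differed with PI-103 only when the replicate number was a block (without doxycycline adjusted p = 0.82, 0.8 and 0.85, and 0.01, 0.006 and 0.013 with the block; with doxycycline 0.5, 0.49 and 0.51, and 0.00061, 4e-04 and 0.00039 with the block). The third of them also passed only with the block with doxycycline in the presence of PI-103 (0.98, and 0.042). The dimmest of the 4, with 17.1 ± 3.68 in control, 14.7 ± 4.63 in PI-103, 18.9 ± 3.48 in dox and 26.3 ± 5.7 in dox+PI-103, was at 1.08-fold with PI-103, higher in 3 of 6 pairs (exact p = 0.719, adjusted p = 0.719). With doxycycline it was at 1.37-fold, higher in 4 of 6 pairs (exact p = 0.125, adjusted p = 0.135). No array of doxycycline on cells without the transgene was analysed here, so the doxycycline comparisons hold both the drug and the transgene.

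**Figure D1:**
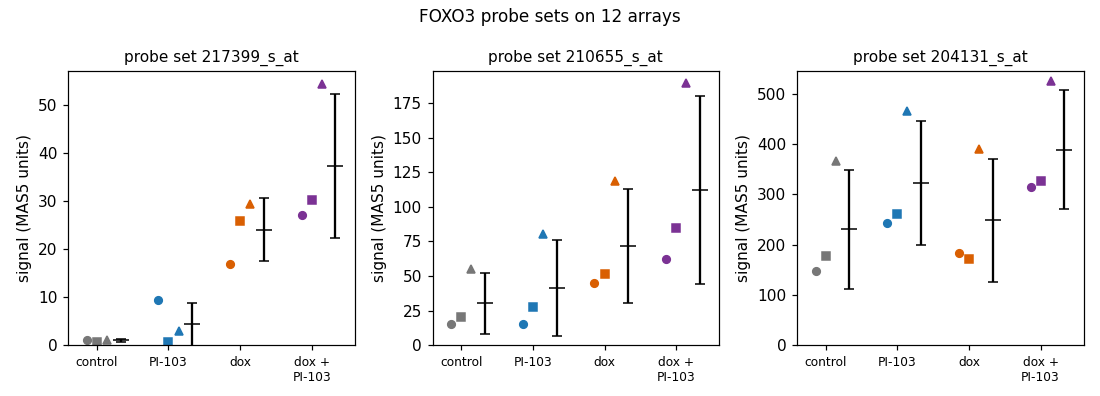
Signal (MAS5 units, linear axes from 0) of 3 FOXO3 probe sets on the 12 arrays, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean ± SD of each group (n = 3). The left and middle panels show probe sets that list FOXO3 and FOXO3B, the right panel one that lists FOXO3 alone, and in the left panel the 6 doxycycline arrays lie above the other 6, with means of 24 and 37.3 against 0.967 and 4.33.

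Doxycycline without PI-103 asked what the induced transgene did while the pathway was active. The FOXO target list shifted up by a small amount, with a median log2 fold change of 0.10 over 33 genes (camera adjusted p = 0.003, and adjusted p = 0.83 with an estimated correlation). None of its members passed over all genes, and 1 rose when adjusted over the list alone. In limma 0 of 13714 genes passed an adjusted p of 0.05, and 147 had an unadjusted p under 0.05. With the replicate number as a block 5 genes passed, named here after their values were seen. YPEL3, a FOXO target, was higher by 1.12 on the log2 scale (block SE 0.14, adjusted p = 0.012), C11orf96 by 0.57 (adjusted p = 0.012) and DBH, the enzyme that makes noradrenaline, by 0.45 (adjusted p = 0.045). SLITRK5 fell by 1.27 (adjusted p = 0.014) and NEFM, a neurofilament gene, fell by 0.46 (adjusted p = 0.045). That blocked count was 0 without replicate number 1, 0 without number 2 and 2 without number 3. The mitosis list (median -0.10, adjusted p = 0.022) and the ribosome biogenesis list (median -0.08, adjusted p = 0.031) shifted down, each with adjusted p = 0.83 with an estimated correlation. The FOXO call ended without control replicate 1 (adjusted p = 0.56) or dox replicate 3 (adjusted p = 0.21), and the mitosis and ribosome biogenesis calls ended without control replicate 1 (0.98 and 0.94), control replicate 2 (0.089 and 0.31) or dox replicate 3 (0.34 for each). The mitosis and ribosome biogenesis calls also ended with median centring (0.12 for each), with no filter (0.069 and 0.091) and without the intensity trend (0.064 for each). With the replicate block the receptors and PI3K pathway list (adjusted p = 0.063 and 0.014 with the block) and the mitochondrial respiration list (0.057 and 0.012 with the block) also passed, each with adjusted p = 0.34 with the block and an estimated correlation.

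PI-103 without doxycycline asked what the inhibitor did to cells with little transgene. PDK4, a kinase that restrains pyruvate dehydrogenase, rose from 35.4 ± 15.1 to 127 ± 8.06 (3.63-fold, adjusted p = 0.014). CCNG2, a cyclin that slows the cell cycle, rose from 721 ± 300 to 1930 ± 390 (2.78-fold, adjusted p = 0.021), and YPEL3 rose 3.15-fold (adjusted p = 0.013). UBALD2 rose 3.24-fold, HBP1, a transcriptional repressor, 3.03-fold, MET, a receptor tyrosine kinase, 2.54-fold and COQ8A 2.47-fold. The other MET probe set gave -0.11 on the log2 scale. Among genes that fell, LIG4, a DNA ligase, went from 326 ± 29.8 to 140 ± 3.35 (adjusted p = 0.0032), MFSD2A from 60.2 ± 11.8 to 23.2 ± 7.34 and POLR3G, an RNA polymerase III subunit, from 143 ± 33.3 to 60.5 ± 10.4. On the log2 scale the other MFSD2A probe set gave -0.03, and the other POLR3G probe set -0.33 against -1.21 for the brightest. The cell cycle inhibitor CDKN1A fell from 233 ± 47.6 to 107 ± 42.3 (adjusted p = 0.049). CDKN1B, another such inhibitor, went from 1190 ± 51.1 to 1800 ± 164 (adjusted p = 0.055 and 3.1e-05 with the block). IRS2, an insulin receptor substrate, went from 2680 ± 141 to 3950 ± 570 (0.15 and 0.00011 with the block), TXNIP from 585 ± 267 to 1070 ± 637 (0.49 and 5.7e-05) and KLF6 from 328 ± 131 to 436 ± 161 (0.76 and 0.0022). Of 4 other KLF6 probe sets 1 gave -0.21 on the log2 scale. RICTOR (log2 fold change 0.86, 0.093 and 6.8e-05), INSR (0.78, 0.19 and 0.00072, with 1 of 4 other probe sets at -0.04) and CCND1 (-0.31, 0.79 and 0.0023) also passed only with the block. In all 163 genes passed, 95 higher and 68 lower, and 30 of them changed at least 2-fold. In the fit with the replicate block 2901 passed, 1558 higher and 1343 lower, and they held all 163. Groups did not overlap for 2381 of the 13714 genes here, and for 622 with doxycycline without PI-103. Chance gives 10% for independent arrays, which these are not, since same-numbered arrays deviate together. Leaving out 1 array moved the count to between 16 (without control replicate 2) and 196 (without control replicate 3). It was 29 without control replicate 1 and 46, 84 and 49 without PI-103 replicates 1, 2 and 3. Of 25 called genes that the naming rule takes, 4 passed without control replicate 2.

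The gene lists moved in both directions with PI-103 alone. The FOXO target list had a median of 0.49 (adjusted p = 7.4e-05, and adjusted p = 0.16 with an estimated correlation). Of its 33 genes 4 rose and 1 fell, or 12 and 2 when adjusted over the list alone, and 17 and 2 with the replicate block. The ATF4 and amino acid response list shifted down (median -0.35, adjusted p = 2.7e-06, and adjusted p = 0.16 with an estimated correlation). In it 3 of 27 genes fell, among them PSAT1, an enzyme of serine synthesis, from 1250 ± 60.9 to 635 ± 142, and CEBPG from 327 ± 51.7 to 192 ± 9.13. PSPH, also of serine synthesis, fell by 0.39 on the log2 scale on its brightest probe set, but another of its probe sets gave 0.62. The unfolded protein response list shifted down (median -0.24, adjusted p = 8.9e-05), with falls of SDF2L1 and of XBP1, a transcription factor of that response, in 2 of 16 genes. XBP1 fell by 0.83 on the log2 scale on its brightest probe set, but its other probe set gave 0.36. The sterol synthesis list did so too (median -0.23, adjusted p = 1e-04), where 1 of 18 genes fell, MSMO1 from 765 ± 83.4 to 386 ± 40.5. Both had adjusted p = 0.16 with an estimated correlation, as had the p53 target list (median -0.18, adjusted p = 0.0025), whose called gene was CDKN1A. These 5 lists passed with each of the 6 arrays left out in turn.

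A further 8 lists passed with PI-103 alone but not when some single array was left out. The DNA replication list had a median of -0.18 (adjusted p = 0.0011, and adjusted p = 0.47 with an estimated correlation) and ended without PI-103 replicate 3 (adjusted p = 0.13). The ribosome biogenesis list had a median of -0.16 (adjusted p = 0.0021, and adjusted p = 0.52 with an estimated correlation) and ended without PI-103 replicate 3 (0.2) or control replicate 1 (0.096). Without control replicate 3, the fatty acid synthesis list (median -0.24, adjusted p = 0.013, and adjusted p = 0.16 with an estimated correlation) ended at 0.056. The glycolysis and hypoxia list (median -0.12, adjusted p = 0.024, and adjusted p = 0.29 with an estimated correlation) ended there at 0.21. Shifts up were seen in the autophagy and lysosome list (median 0.15, adjusted p = 0.026, and adjusted p = 0.35 with an estimated correlation), with rises of PIK3C3, 1.58-fold, and ATG14, 1.48-fold. Of 4 other PIK3C3 probe sets 1 went the other way (-0.22 on the log2 scale). That call ended without control replicate 1 (0.096) or PI-103 replicate 2 (0.099), and with the mean of probe sets (0.42). The cell cycle brakes list (median 0.30, adjusted p = 0.037, and adjusted p = 0.16 with an estimated correlation) held CCNG2, which rose, and CDKN1A, which fell. It ended without control replicate 1 (0.076), PI-103 replicate 1 (0.077) or PI-103 replicate 2 (0.094), with the stricter filter (0.059) and with the mean of probe sets (0.082). The mitosis list (median 0.20, adjusted p = 0.026, and adjusted p = 0.66 with an estimated correlation) held 1 gene that rose, CDC25C. It ended without PI-103 replicate 1 (0.56), PI-103 replicate 2 (0.12) or control replicate 3 (0.7), and with median centring (0.08). The ribosomal protein list (median 0.14, adjusted p = 0.043, and adjusted p = 0.66 with an estimated correlation) ended under quantile normalization (0.24), median centring (0.22), the stricter filter (0.058), the mean of probe sets (0.27) and no intensity trend (0.056), and without PI-103 replicate 1 (0.59), PI-103 replicate 2 (0.055) or control replicate 3 (0.56). With the replicate block the receptors and PI3K pathway list (adjusted p = 0.058 and 0.036 with the block) and the antioxidant list (0.06 and 0.035 with the block) also passed, with adjusted p = 0.18 and 0.4 with the block and an estimated correlation.

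PI-103 with doxycycline asked the same of cells with the transgene on. PDK4 rose from 53 ± 8.66 to 626 ± 235 (10.9-fold, adjusted p = 0.00014). PIK3IP1, a negative regulator of PI3K, rose from 29.3 ± 11.5 to 212 ± 41.9 (7.13-fold, adjusted p = 0.00036), and its other 2 probe sets gave -0.04 and 1.97 on the log2 scale. NDRG1 rose 5.34-fold. Some genes rose from a signal near the filter level of 7.62, where a fold depends on the offset, so their levels are given. HS3ST3B1 went from 6.23 ± 5.46 to 74.4 ± 35 (log2 fold change 0.37 on its other probe set), YPEL4 from 11.3 ± 8.86 to 104 ± 1.22, DLX2, a homeobox gene, from 7.87 ± 4.65 to 83.1 ± 44.8 and FBXO32, a ubiquitin ligase of muscle wasting, from 6.33 ± 3.67 to 40.5 ± 6.09. RICTOR, a core part of mTORC2, rose from 293 ± 61.8 to 894 ± 72.2, and INSR, the insulin receptor, from 151 ± 48 to 299 ± 40.4. BCL2L11, which encodes the pro-apoptotic BIM, rose from 262 ± 39.5 to 393 ± 53.3 (adjusted p = 0.023), though of its 6 other probe sets 1 gave -0.03 on the log2 scale. CDKN1B rose from 1260 ± 177 to 2180 ± 319 (adjusted p = 0.0037). Passing only with the block were CCND1 (log2 fold change -1.13, adjusted p = 0.052 and 6.3e-08 with the block), PMAIP1 (-0.74, 0.074 and 0.0012), IRS2 (0.48, 0.094 and 9.4e-05), TXNIP (0.85, 0.3 and 8.6e-06) and KLF6 (0.75, 0.32 and 7.7e-06). Falls were seen in KRT19, a keratin, from 20.3 ± 4.91 to 2.60 ± 1.76, in FJX1 from 93.2 ± 24.3 to 24.0 ± 6, in CHAC2 from 443 ± 75.3 to 129 ± 25, and in HK2, a hexokinase, from 913 ± 101 to 304 ± 59.9. That HK2 probe set gave -1.59 on the log2 scale, and its other 2 gave -0.44 and -0.27. CDC25A, a phosphatase that drives the cell cycle, fell from 327 ± 139 to 96.0 ± 40.7. In all 1227 genes passed, 646 higher and 581 lower, and 4588 with the replicate block, 2197 higher and 2391 lower, which held all 1227. Leaving out 1 array gave between 604 (without dox replicate 1) and 1190 genes (without dox replicate 3), with 643 without dox replicate 2 and 705 and 775 without dox+PI-103 replicates 1 and 2. Of the 95 genes that rose with PI-103 alone 91 also rose here, and of the 68 that fell 65 also fell, where independent lists would share 4.47 and 2.88. The fold changes of these comparisons share no array, but their calls use 1 spread per gene from all 12 arrays. Genes with a small spread are more easily called in both, so the numbers for independent lists may be too low.

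The FOXO target list had a median of 0.85 with PI-103 in the presence of doxycycline (adjusted p = 9.7e-11, and adjusted p = 0.1 with an estimated correlation). Of its 33 genes 19 rose and 2 fell, or 23 and 3 when adjusted over the list alone. The DNA replication list shifted down (median -0.41, adjusted p = 2.3e-07, and adjusted p = 0.31 with an estimated correlation). In it 9 of 33 genes fell, or 15 when adjusted over the list alone, among them GINS1 from 950 ± 99.3 to 537 ± 81 and POLE2 from 414 ± 45.4 to 247 ± 5.14. With the replicate block this list passed also with an estimated correlation (adjusted p = 0.0073). The ATF4 list (median -0.42, adjusted p = 8.7e-05, and adjusted p = 0.18 with an estimated correlation) had 7 of 27 genes lower, with PSAT1 from 1050 ± 101 to 392 ± 56.1. The unfolded protein response list (median -0.18, adjusted p = 4e-04) had 6 of 16 genes lower and 1 higher, with MANF from 1130 ± 8.81 to 598 ± 145. The sterol synthesis list (median -0.35, adjusted p = 0.00071) had 2 of 18 lower, MSMO1 and HMGCS1, and both of these lists had adjusted p = 0.22 with an estimated correlation. In the fatty acid synthesis list (median -0.52, adjusted p = 0.0019, and adjusted p = 0.12 with an estimated correlation) 3 of 10 genes fell, FASN, ACACA and SREBF1. The ribosome biogenesis list (median -0.33, adjusted p = 0.0019, and adjusted p = 0.61 with an estimated correlation) had 2 of 23 lower, PNO1 and NOP16, and ended without dox+PI-103 replicate 3 (adjusted p = 0.066). The MAPK response list shifted up (median 0.46, adjusted p = 0.0019, and adjusted p = 0.1 with an estimated correlation). In it 4 of 21 genes rose, with EGR1 from 225 ± 12.9 to 819 ± 323 and DUSP6, a phosphatase that dampens ERK, from 294 ± 101 to 1030 ± 134. The autophagy and lysosome list (median 0.26, adjusted p = 0.0035, and adjusted p = 0.22 with an estimated correlation) had 5 of 25 genes higher, PIK3C3, ATG14 and ATG12 among them, and ended with the mean of probe sets (0.085). ATG12 rose by 0.5 on the log2 scale on its brightest probe set, and its other 2 gave 0.03 and 0.38.

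Doxycycline with PI-103 asked what the transgene did while the pathway was inhibited. PDK4 rose from 127 ± 8.06 to 626 ± 235 (4.6-fold, adjusted p = 0.016) and PIK3IP1 from 35.8 ± 6.19 to 212 ± 41.9 (5.64-fold, adjusted p = 0.016), while its other 2 probe sets gave -0.16 and 2.15 on the log2 scale. TMEM100 rose 5.02-fold, PCDH17, a protocadherin, 4.10-fold, ADAMTS1, a secreted protease, 3.92-fold, MXRA8 3.59-fold and SELENOP, a selenium transport protein, 3.51-fold (log2 fold change 0.31 on its other probe set). SESN1, a sestrin, rose from 136 ± 13.9 to 308 ± 35 and TP53INP1, a p53-induced gene of autophagy, from 246 ± 21.4 to 525 ± 40.6. The 7 genes that fell were LZTS1 from 92.2 ± 4.67 to 43.4 ± 10.3, LIMD1 from 210 ± 22.2 to 114 ± 3.63, GPRC5B from 78.0 ± 4.28 to 45.5 ± 5.31, MAT2A, which makes S-adenosylmethionine, from 756 ± 47.5 to 458 ± 18, HS6ST2 from 1340 ± 95.7 to 860 ± 22.7, NES, which encodes nestin, from 332 ± 21 to 220 ± 4.92, and AHCTF1 from 438 ± 22.1 to 300 ± 14.6. Of the 2 other LZTS1 probe sets 1 gave 0.20 on the log2 scale. MAT2A fell by 0.72 on its brightest probe set and by 0.2 on its other one. Some genes passed only with the replicate block: SESN3 (log2 fold change 1.55, adjusted p = 0.075 and 6.9e-05 with the block), BCL2L11 (0.62, 0.093 and 0.0019), RICTOR (0.94, 0.11 and 7.7e-05), INSR (0.75, 0.33 and 0.0016), CDKN1B (0.27, 0.63 and 0.012), TXNIP (0.36, 0.95 and 0.02), KLF6 (0.28, 0.96 and 0.031) and CCND1, which encodes cyclin D1 (-0.87, 0.41 and 6.5e-06). In all 53 genes passed, 46 higher and 7 lower, and with the replicate block 1657, 795 higher and 862 lower, which held all 53. Leaving out any of the arrays of replicates 1 and 2 gave 0 genes, and 60 and 59 passed without PI-103 and dox+PI-103 replicate 3. Those runs had no block, so the loss of an array and unequal replicate numbers cannot be told apart in them. Without the intensity trend in limma's prior 0 genes passed.

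The FOXO target list had a median of 0.62 with doxycycline in the presence of PI-103 (adjusted p = 6.3e-16, and adjusted p = 0.036 with an estimated correlation). With the block and an estimated correlation its adjusted p was 0.061. Of its 33 genes 2 rose, PDK4 and SESN1, or 15 when adjusted over the list alone, and 18 with the replicate block. The MAPK response list also passed both ways (median 0.30, adjusted p = 0.00059, and adjusted p = 0.036 with an estimated correlation), but had adjusted p = 0.21 with the block and an estimated correlation. The DNA replication list shifted down (median -0.26, adjusted p = 1.8e-06, and adjusted p = 0.47 with an estimated correlation). Of its 33 genes 0 passed, 1 was lower when adjusted over the list alone, and 16 were lower with the replicate block. With the block the list passed with an estimated correlation (adjusted p = 0.0051). The autophagy and lysosome list shifted up (median 0.16, adjusted p = 0.00059, and adjusted p = 0.29 with an estimated correlation). The mitosis list (median -0.24, adjusted p = 0.00061, and adjusted p = 0.65 with an estimated correlation) ended without PI-103 replicate 1 (0.22) or dox+PI-103 replicate 3 (0.68). The ribosome biogenesis list (median -0.17, adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation) ended without the same arrays (0.51 and 0.46). The p53 target list (median 0.14, adjusted p = 0.013, and adjusted p = 0.35 with an estimated correlation) had SESN1 and TP53INP1 higher. It ended with the replicate block (0.061), and without PI-103 replicate 1 (0.09), dox+PI-103 replicate 2 (0.075) or PI-103 replicate 3 (0.14). The receptors and PI3K pathway list (median 0.03, adjusted p = 0.049, and adjusted p = 0.58 with an estimated correlation) held 1 called gene, PIK3IP1. It ended without PI-103 replicate 1 (0.26), dox+PI-103 replicate 1 (0.052) or dox+PI-103 replicate 3 (0.13), and without the intensity trend (0.073).

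**Figure D2:**
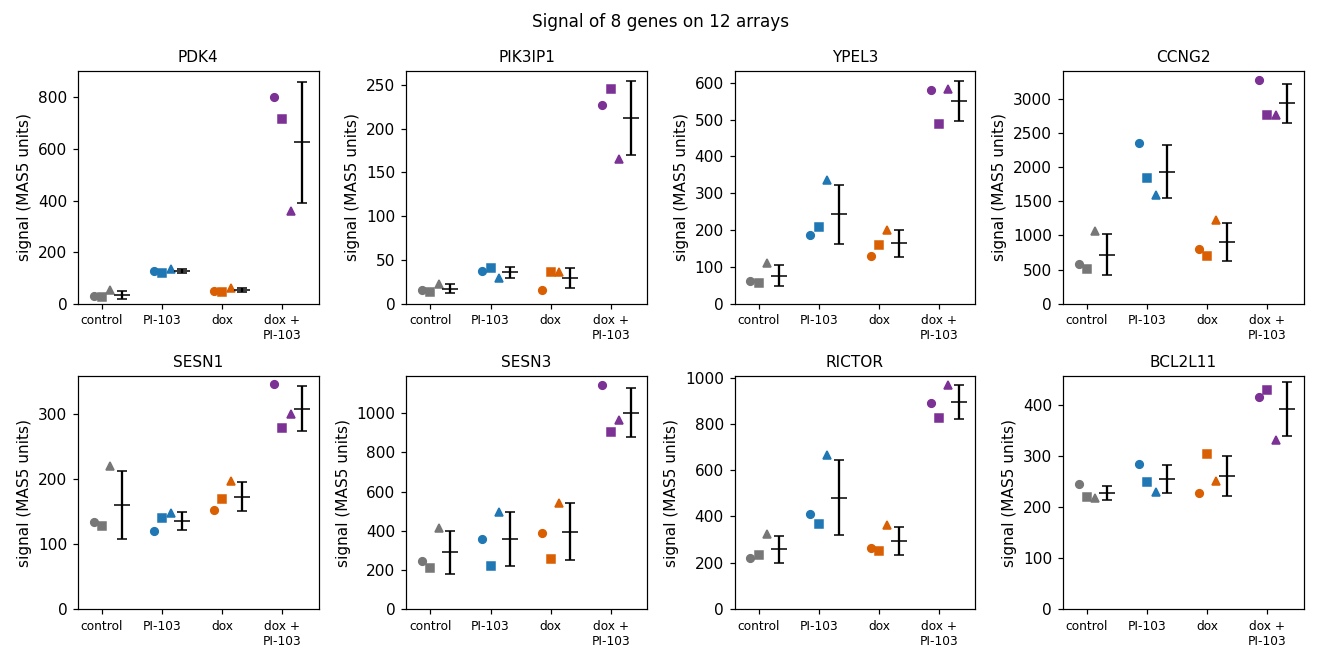
Signal (MAS5 units, linear axes from 0) of 8 genes on the 12 arrays, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean ± SD of each group (n = 3). PDK4 has means of 35.4, 127, 53 and 626 in control, PI-103, dox and dox+PI-103, and each of the 8 genes has its highest mean in dox+PI-103. The 8 were picked for display from the named genes, so their common pattern is no separate result. Of the 33 tested FOXO list genes, 19 rose and 2 fell with PI-103 in the presence of doxycycline.

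**Figure D3:**
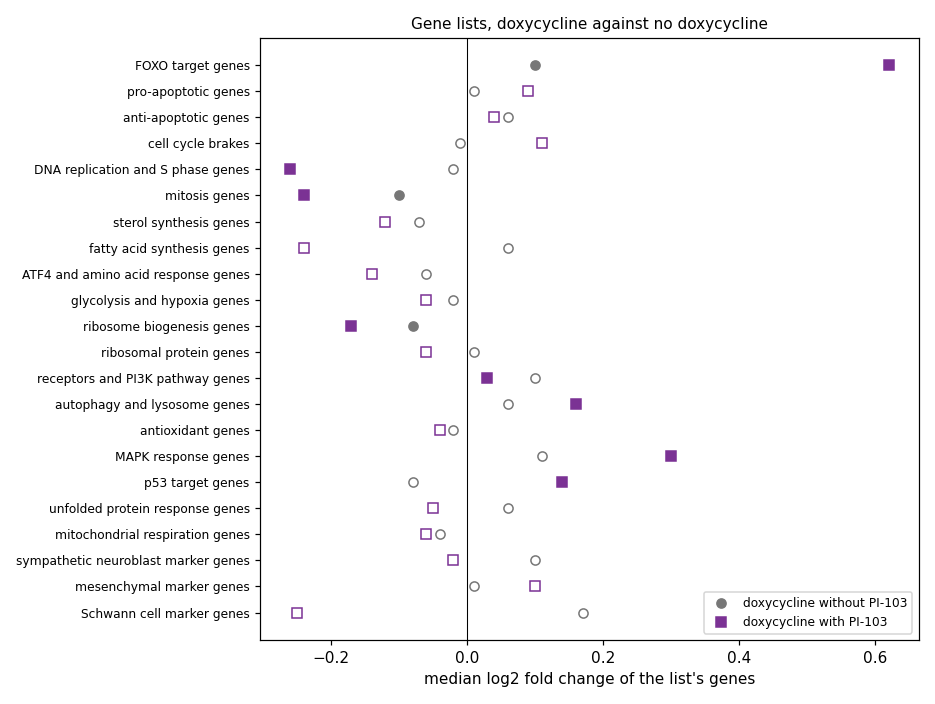
Median log2 fold change with doxycycline of the tested genes of each of 22 lists, without PI-103 (circles) and with PI-103 (squares), filled where the camera adjusted p was under 0.05. The FOXO target list lies at 0.10 without PI-103 and at 0.62 with PI-103.

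Whether the doxycycline response differed with PI-103 was tested as an interaction. In limma 0 genes passed, and 369 had an unadjusted p under 0.05. When the replicate number was a block 97 passed, 70 with a positive and 27 with a negative log2 difference between the doxycycline effects with and without PI-103, and without replicate number 3 the blocked count was 156. It was 2 without replicate number 1 and 2 without replicate number 2. Named after their values were seen, those with the smallest blocked adjusted p included ADAMTS1 (log2 difference 1.97, adjusted p = 0.00066), SLF1 (0.73, adjusted p = 0.0074), COL3A1, a fibrillar collagen (1.65, adjusted p = 0.0082), SULT1C4 (1.56, adjusted p = 0.0082) and ARID5B (1.17, adjusted p = 0.0089) above 0. CCND1 (-0.82, adjusted p = 0.00098), FEN1, a replication nuclease (-0.61, adjusted p = 0.0074), MAT2A (-0.67, adjusted p = 0.013) and the sympathetic transcription factors GATA2 (-0.50, adjusted p = 0.014) and PHOX2A (-0.48, adjusted p = 0.02) lay below 0. The other probe sets of SLF1 and MAT2A gave only 0.14 and -0.13. RICTOR (0.76, adjusted p = 0.032) and SESN3 (1.10, adjusted p = 0.046) passed with the block, and BCL2L11 did not (0.43, adjusted p = 0.26). The FOXO target list differed upwards at the preset correlation (median 0.28, adjusted p = 5.3e-10), and did so with each of the 12 arrays left out. It did not pass with an estimated correlation (adjusted p = 0.12, and 0.16 with that and the block). In each of replicates 1, 2 and 3 its median doxycycline effect was 0.18, 0.13 and 0.09 without PI-103, against 0.55, 0.52 and 0.52 with PI-103. The DNA replication list differed downwards (median -0.22, adjusted p = 1.5e-05, and adjusted p = 0.56 with an estimated correlation), and was the only list of the 22 to pass with both the block and an estimated correlation (adjusted p = 0.0052). It ended without control replicate 3 (0.076) or dox+PI-103 replicate 3 (0.089). The mitosis list differed with the block only (adjusted p = 0.16 and 0.0069 with the block, and adjusted p = 0.46 with the block and an estimated correlation).

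Averaged over the other treatment, doxycycline changed 10 genes, 9 higher and 1 lower, and 1353 with the replicate block. PDK4 rose 2.66-fold and PIK3IP1 2.98-fold, each with an adjusted p of 0.044. PI-103 changed 2037 genes, 1045 higher and 992 lower, and 5480 with the replicate block. With 1 array left out the doxycycline count was 0 without replicate 1 or 2 of control, of PI-103 or of dox+PI-103, and without dox replicates 2 and 3. It was 1 without dox replicate 1, 5 without PI-103 replicate 3, 21 without dox+PI-103 replicate 3 and 39 without control replicate 3. Both treatments together against control changed 1698 genes, 896 higher and 802 lower, and 5130 with the replicate block. The larger changes there included PDK4, 16.7-fold higher, and PIK3IP1 11.3-fold. YPEL4 went from 10 ± 9.6 to 104 ± 1.22 and HTR2B, a serotonin receptor, from 5.43 ± 2.42 to 53.7 ± 22.9. FJX1 fell by 2.37 and TNFRSF12A fell by 2.29 on the log2 scale. That count was 862 without control replicate 1, 901 without control replicate 2 and 1039 without dox+PI-103 replicate 1.

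Across 13714 genes, the averaged doxycycline and PI-103 effects had a Pearson r of 0.401 and a Spearman rho of 0.387, with a covariance of 0.0288 against -0.0001185 in simulated unchanged groups. Genes are not independent replicates. That r was 0.2402 without dox replicate 3, and 0.2402 with no filter. The effects of each treatment alone, which share the control arrays, had r = 0.375, where simulated unchanged groups gave 0.4996. Their covariance was 0.0273, against 0.0469 in those simulations and 0.0234 in simulations with the spread left by the replicate block, which fit the pairing and were chosen after seeing the data. So the shared control arrays alone could give most or all of that covariance, and it is not read as a shared response. Those arrays are too few to split. The doxycycline effects without and with PI-103, which share no array, had r = 0.228, and the PI-103 effects without and with doxycycline r = 0.611. These were 6 relations in all.

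**Figure D4:**
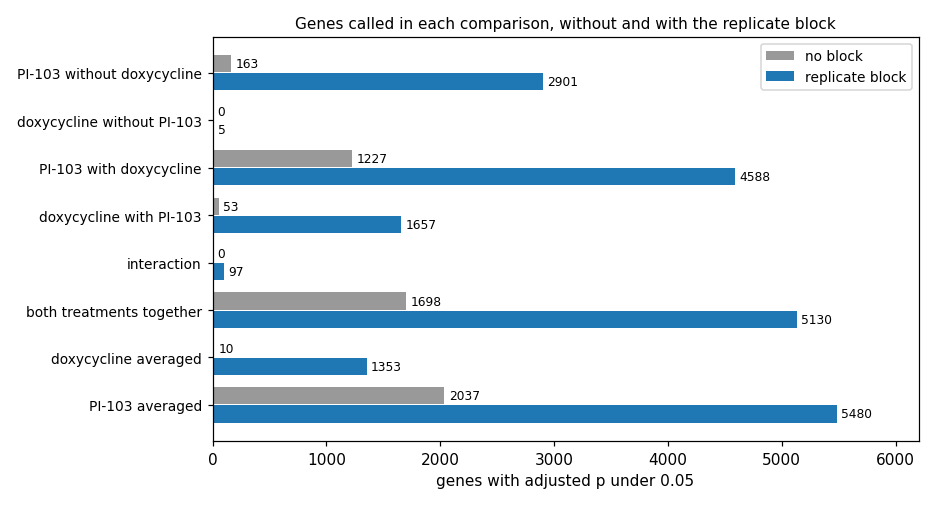
Genes with an adjusted p under 0.05 in each of 8 comparisons (bars from 0), in limma without a block (grey) and with the replicate number as a block (blue). Doxycycline called 0 and 5 genes without PI-103 and 53 and 1657 with PI-103.

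The pro-apoptotic and anti-apoptotic lists passed in none of the 5 comparisons above. PMAIP1, which encodes NOXA, went from 910 ± 119 in control to 548 ± 131 in PI-103 (adjusted p = 0.17 and 0.0024 with the block). MYCN had a low signal, 23.9 ± 12 in control, and rose with both treatments together to 58 ± 10.5 (log2 fold change 1.30, limma adjusted p = 0.029). That rests on 1 of 3 probe sets, since the other 2 gave 0.09 and 0.64 there, and -0.05 each with doxycycline in the presence of PI-103. On its brightest probe set MYCN passed with PI-103 in the presence of doxycycline (adjusted p = 0.1 and 0.0013 with the block) and with doxycycline in the presence of PI-103 (0.44 and 0.0099 with the block) only with the block. Lists of sympathetic neuroblast, mesenchymal and Schwann cell markers did not pass in any of these comparisons either, with adjusted p from 0.11 for the mesenchymal list, with doxycycline in the presence of PI-103, upward. RNA quality was read from the 3 prime over 5 prime probe set ratios. The ACTB ratio was 1.18-fold higher with PI-103, in 5 of 6 pairs (two-sided exact sign-flip test, p = 0.0938), and the GAPDH ratio was 0.995-fold, higher in 3 of 6 pairs (exact p = 0.688). This test too takes the 6 pairs of 3 replicate numbers as independent. The ACTB differences went by number, so its p may be too small. Replicate number 3 stood apart, with an ACTB ratio of 1.80 ± 0.0645 over its 4 arrays against 3.71 ± 0.763 and 4.01 ± 0.551 for numbers 1 and 2. Without replicate number 3, PI-103 alone changed 652 genes, doxycycline alone 2, PI-103 with doxycycline 2339 and doxycycline with PI-103 373, an alternative chosen after seeing the data.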

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

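The tests of transgene mRNA and of the ATF4 list, of the GAPDH ratio and of PI-103 calls that follow the ACTB ratio, and of the splits and regroupings that keep the replicate pairs were chosen only after the result was seen.

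The effect of doxycycline with PI-103 differed from that without it, by a test of the interaction, in 5 gene lists at the preset correlation and, with the replicate block only, in a count of genes. The p53 list and the autophagy and lysosome list share members with the FOXO target list, so these are not 5 separate findings. For the FOXO target list the adjusted p was 5.3e-10, for the DNA replication list 1.5e-05, for the p53 target list 0.0056, for the MAPK response list 0.012 and for the autophagy and lysosome list 0.026. With an estimated correlation these were 0.12, 0.56, 0.34, 0.12 and 0.45, and with that and the replicate block 0.16, 0.0052, 0.23, 0.37 and 0.16. Without a block 0 genes had an interaction. With the replicate block 97 had one, but 2 without replicate number 1, 2 without number 2 and 156 without number 3. The DNA replication call ended without control replicate 3 (adjusted p = 0.076) or dox+PI-103 replicate 3 (0.089), and the p53 call without control replicate 2 (0.1) or PI-103 replicate 3 (0.079). The MAPK call ended without dox+PI-103 replicate 1 (0.054), control replicate 3 (0.061) or PI-103 replicate 3 (0.11). The autophagy call ended without PI-103 replicate 1 (0.13), dox replicate 1 (0.25), control replicate 2 (0.1), dox+PI-103 replicate 2 (0.18), control replicate 3 (0.076), PI-103 replicate 3 (0.061) or dox+PI-103 replicate 3 (0.052), and with no filter (0.061).

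More transgene mRNA with PI-103 was tested as the whole of the larger response, taking the FOXO list to rise in proportion to transgene signal. The highest ratio of the transgene probe sets' rises, with over without PI-103, was 1.84, which would take the FOXO list mean from 0.16 to 0.29. The list mean was 0.60, an excess of 0.30 (SE of the list mean 0.069). That SE leaves out the error of the mean without PI-103 (SD 0.082 over the replicates), and a steeper response was not tested. So the excess argues against more transgene mRNA only under proportion, and does not exclude it. A wider spread among the pairs without PI-103 was tested by a ratio of median SDs, without over with PI-103, which was 0.962. This ratio decides nothing, since the fit gives both doxycycline comparisons 1 shared spread per gene. A mitochondrial stress response to doxycycline itself would raise the ATF4 list, whose median in the averaged doxycycline comparison was -0.07 (camera adjusted p = 0.032, 0.068 with the block, and adjusted p = 0.59 with an estimated correlation). A candidate explanation is that PI-103 and induced FOXO3A act on the same genes. The PI-103 effect without doxycycline and the doxycycline effect with PI-103 had r = 0.052 across genes. Simulated unchanged groups gave -0.504, but real effects widen both spreads, so the 2 values of r are not on a par. Their covariance was 0.00539, against -0.0475 in those simulations and -0.0234 with the spread left by the block. The mirrored relation, doxycycline without PI-103 against PI-103 with doxycycline, had r = -0.067 (covariance -0.00635, against -0.0469 and -0.0239). The r of 0.052 is small and does not separate released FOXO3A from other effects of PI-103, which stay open. The drug doxycycline stays open too, since cells without the transgene were not analysed here.

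The ACTB ratio was higher with PI-103 in 5 of 6 pairs. Lower RNA integrity would raise the GAPDH ratio too, and it was higher in 3 of 6 pairs. This cannot decide, since the GAPDH ratio moves little. It was 1.06, 1.04 and 0.951 in replicate numbers 1, 2 and 3, where the ACTB ratio was 3.71, 4.01 and 1.80. The GAPDH differences with PI-103 had an SD of 0.0395 on the log2 scale over the 6 pairs. If the PI-103 calls followed the ACTB ratio, they would be lost in replicate number 3, where its log2 ratio changed by -0.11 and 0.05 with PI-103, against a mean of 0.38 in numbers 1 and 2. Over the 4650 genes called without number 3, with the block, the slope of the number 3 difference on the mean of numbers 1 and 2 was 0.65 without and 0.88 with doxycycline. That argues against the ratio as the source of these calls as a whole. A cause in the ACTB transcript itself was not tested.

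Other splits of the arrays were fitted for each count. With 6 arrays there are 10 splits, too few for a share under 0.05. The real split gave 163 genes for PI-103 without doxycycline, 1227 with doxycycline, 53 for doxycycline with PI-103 and 1698 for both together, against at most 0 in the others, so 1 of 10 each time. For doxycycline without PI-103 it gave 0, as did all 10. Averaged over doxycycline, PI-103 gave 2037 genes, and 1 of 100 drawn splits, the real one, gave as many (highest other 1519). Those splits ignore the replicate pairs. Of the 32 splits that part every pair 1, the real one, gave as many without the block (highest other 0), and 1 gave as many as the real 5480 with the block (highest other 1634). Averaged over PI-103, doxycycline gave 10 genes, and 3 of 100 splits gave as many, but the highest other gave 645, many times the real count, which points to a structure of the samples. Of the 32 splits that part every pair 1 gave as many as the real 10 without the block (highest other 0), and 1 as many as the real 1353 with the block (highest other 677). For the blocked interaction 3 of 100 regroupings gave 97 or more, the real one included, with a highest other of 520, which again points to structure. Among splits that part every pair, the share was under 0.05 for both averaged counts, with and without the block. That share, 1 of 32, is the smallest those splits allow. For the blocked interaction the share among the regroupings was under 0.05 too, but 100 draws are too few to place 3 of 100 clearly below it. Such shares do not make the 10 genes stable, since 0 passed in 8 of the 12 runs with 1 array left out. Nor do they make the blocked interaction stable, whose count fell from 97 to 2 without replicate number 1 or number 2.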

How the results depend on the processing

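The runs without a whole replicate number, and camera with both a replicate block and an estimated correlation, were chosen only after the result was seen. Below, counts of genes are for PI-103 without doxycycline, doxycycline without PI-103, PI-103 with doxycycline, doxycycline with PI-103, the interaction, both together, doxycycline averaged and PI-103 averaged, in that order: 163, 0, 1227, 53, 0, 1698, 10 and 2037. The replicate block gave 2901, 5, 4588, 1657, 97, 5130, 1353 and 5480. The block removes the spread between replicate numbers, and of 100 calls of named genes it lost 0. Of 38 list calls in the first 5 comparisons it lost 1, that of the p53 list in doxycycline with PI-103, and the calls it added there, for the 15 genes always named and for the lists, stand beside them. Without replicate number 3 the counts were 652, 2, 2339, 373, 15, 2932, 215 and 3114. With the block they were 1401, 0, 2997, 573, 2, 3717, 394 and 4076 without number 1, then 1610, 0, 3111, 495, 2, 3835, 302 and 4220 without number 2, and 2102, 2, 3980, 1468, 156, 4459, 993 and 4650 without number 3. Asking for a 2-fold change gave 30, 0, 241, 22, 0, 373, 2 and 146. With only the groups compared, which leaves fewer arrays for the spread, the first 4 and both together gave 6, 0, 723, 4 and 1045, and the interaction and averaged comparisons, which use all groups, have no such value. Every probe set on its own gave 1898 for PI-103 with doxycycline, 2756 for both together, 1 for doxycycline averaged and 3443 for PI-103 averaged. For PI-103 without doxycycline, quantile normalization gave 247, median centring 92, the mean of probe sets 107 and no intensity trend 78. For doxycycline with PI-103 quantile normalization gave 103, the mean of probe sets 33 and no intensity trend 0. For doxycycline averaged an offset of 8 gave 22, quantile normalization 41, the stricter filter 38, and no filter, the mean of probe sets and no intensity trend 0. With 1 array left out the ranges were 16 to 196, 0 to 0, 604 to 1190, 0 to 60, 0 to 0, 862 to 1680, 0 to 39 and 1454 to 2175. The correlation of the averaged effects, 0.4009, was 0.4789 with an offset of 8, 0.2402 with no filter, 0.5807 with the stricter filter, 0.3554 over every probe set, and 0.2402 to 0.507 with 1 array left out, against an SD of 0.032 over replicate numbers left out. Of the list tests 66 passed, 71 with the replicate block, 57 to 80 with 1 array left out, 4 with an estimated correlation and 6 with that and the replicate block. In doxycycline without PI-103 the mitosis list turned direction without dox replicate 3 (adjusted p = 0.34), and the ribosome biogenesis list without control replicate 1 (0.94) or dox replicate 3 (0.34). With 1 array left out their adjusted p ran from 4.6e-07 to 0.98 and from 2e-06 to 0.94. Those runs had no block and left the replicate numbers unequal between groups. Within replicates 1, 2 and 3 the list medians kept their direction. They were -0.07, -0.05 and -0.19 for mitosis and -0.11, -0.06 and -0.11 for ribosome biogenesis. Of 100 calls of named genes, 99 passed with an offset of 0.5 and 99 with 8, 95 with quantile normalization, 83 with median centring, 66 without the intensity trend, 65 with the mean of probe sets, 50 with only the groups compared and 100 with the replicate block, and no call turned direction. No direction of a list past the threshold turned under either scaling alternative. Apart from the block and the smaller set of arrays, the cause was not tested. Signal over background limits the dim genes, and no detection call was used here.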

Other observations

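The chaperone and tubulin lists were written after their prompting genes were seen, and before the other members were tested.

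In the averaged PI-103 comparison, chaperones and tubulins were read because DNAJA1 and STIP1, both of the heat shock machinery, and TUBB6 and TUBB2A were among the genes with the smallest adjusted p that fell. Without those prompting genes, 4 of 21 chaperone genes fell and 1 rose, or 9 and 2 with the replicate block. DNAJB1 fell by 0.87 on the log2 scale (SE 0.15, adjusted p = 0.0026), HSPH1 fell by 0.72 and HSPE1 fell by 0.54, whereas HSP90AA1, at 0.04, and the CCT subunits, at -0.03 to 0.11, did not pass. With the block CCT8 passed, at 0.11 (adjusted p = 0.49 and 0.023 with the block). The hypothesis that heat shock chaperone genes fall together with PI-103 had a camera p of 0.027 with a median of -0.06, and p = 0.4 with an estimated correlation (0.19 with that and the replicate block), so it may rest on a few co-regulated members. Of 14 genes of tubulins and their cofactors 3 fell, or 6, with 1 higher, with the block: TUBB4B fell by 0.56 (adjusted p = 0.00016), TUBG1 fell by 0.45 and TUBB3, the neuronal beta tubulin, fell by 0.35. The hypothesis that tubulin genes fall together with PI-103 had a camera p of 0.02, and p = 0.039 with an estimated correlation, but p = 0.11 with that and the replicate block. With PI-103 in the absence of doxycycline the tubulin list had a median of -0.06 (camera p = 0.099, and p = 0.12 with an estimated correlation). In the presence of doxycycline its median was -0.18 (camera p = 0.0067, and p = 0.02 with an estimated correlation). The tubulin list also moved down with doxycycline in the presence of PI-103 (median -0.14, p = 0.00018, and p = 0.0041 with an estimated correlation). There 0 of its 14 genes passed, and 5 fell with the block. These lists were tested on the data that prompted them.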
